A study of Mus musculus with 6 samples.

How the data were processed

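RNA of hearts from 3 young and 3 old male mice was measured by sequencing; the labels also carry an extraction text that refers to another sample type, abbreviated NRVMs. Per the submitters' processing notes, the authors aligned reads with HISAT2 to GRCm38.p6 and counted reads per gene with featureCounts of the Subread package. The deposited counts are whole numbers of reads per gene. The authors also deposited FPKM values for 13170 genes, made from counts by scaling to gene length and depth; their scale differed from the count totals by up to −9.58% (old 1). Tool versions, annotation release, strand and multi-mapping settings are not given in the sources used here.

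The count table held 44200 gene models, 43629 with a name and 571 without; the latter were left out of the comparison and counted apart. Of the named models 42548 were found by identifier in GENCODE M21 and 1081 were not, and 25 names that had been turned into dates were read by identifier. No read fell on 19670 models. Libraries held 13673856 to 15583364 counts. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed by edgeR's filterByExpr, libraries were scaled by TMM, and old was compared with young by quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.187.

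Gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the lists of pan-leukocyte and imprinted genes and the alternatives named as added below. The rule named the 8 largest rises and 8 largest falls among genes that passed, had a mean CPM of at least 1 and groups without overlap, leaving out predicted models; the 2 members of each list with the smallest p; and 10 genes of cardiac ageing. Results of 2 of these genes are not reported here. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. A list adjusted alone uses the p values of its members only. Some genes belong to several lists, so the lists are not independent. Single values per library were compared by exact permutation, where 3 against 3 allow no p under 0.1. The methods were tested on simulated data with 3 libraries per group. There edgeR made 9 false calls (8.2% of its calls), DESeq2 30 (20.7%) and limma-voom 6 (5.8%). For a list lowered by 0.5 log2 units the adjusted p was 1.69e-19 with camera, 0.0804 with an estimated correlation and 0.077 with fry. The simulated data had no correlation between genes, the same spread at both ages and far fewer changed genes than were called here. These values therefore need not hold for the hearts. Alternatives were RLE and upper-quartile factors, other filters, DESeq2, limma-voom, limma-trend on FPKM, the replicate number as a block and each library left out. Added after seeing the data were the inclusion of gene models without a name and the removal of length and GC trends, alone and with the replicate block. In the test of the genes beside Ide and Fgfbp3, a pseudogene inside Ide was first counted as a neighbour and then left out; the reading of the test was the same.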

Results

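Hearts of male C57BL/6 mice were compared at 2 ages, 2 months (young) and 22 months (old), to find the genes whose RNA levels differ with age. Each age was represented by 3 hearts from separate animals, and total RNA of heart tissue was sequenced. The libraries held between 13673856 and 15583364 counted reads. Replicates were more alike in young hearts. Pearson's r of log2 CPM across genes lay between 0.985 and 0.988. In old hearts it lay between 0.958 and 0.978. Genes are not independent replicates in these correlations. The median SD of a gene's log2 CPM was 0.14 in young and 0.27 in old hearts. The first principal component held 56% of the variance and separated the ages. The library old 1 (15 on this component) lay nearer to the young libraries (−38.3, −37.1 and −33.4) than old 2 and old 3 did (45.9 and 48). Values below are mean CPM ± SD with n = 3 per age, and log2 fold changes of old over young ± SE. The SE is approximate, the absolute log2 fold change divided by the square root of the F statistic of edgeR's test. Adjusted p values of genes come from edgeR's quasi-likelihood test, and those of gene lists from camera, both with Benjamini-Hochberg adjustment. Coordinates are those of GRCm38.

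Immune and interferon-induced genes were among those with the largest rise in old hearts, and the apelin receptor gene was among those with the largest fall. Slfn4, an interferon-induced Schlafen gene, rose from 0.224 ± 0.0419 to 33 ± 32.8 CPM (log2 fold change 7.15 ± 0.90, edgeR adjusted p = 0.00242; ENSMUSG00000000204, chromosome 11, 83175186 to 83190216). Aplnr, the receptor of the peptide apelin on endothelial cells, fell from 47.7 ± 6.85 to 8.52 ± 0.764 CPM (log2 fold change −2.48 ± 0.16, edgeR adjusted p = 0.000197; ENSMUSG00000044338, chromosome 2, 85136225 to 85139923). Snhg11, a host gene of small nucleolar RNAs, went from 0.594 ± 0.348 to 31.3 ± 7.78 CPM (ENSMUSG00000044349, chromosome 2, 158375638 to 158386145). The chemokine Ccl8 went from 0.286 ± 0.249 to 9.28 ± 2.6 CPM (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799).

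Among 14413 genes tested, 2174 (15.1%) had an edgeR adjusted p under 0.05, of which 1257 were higher and 917 lower in old hearts. A change of at least 2-fold was found in 818 of them, 589 higher and 229 lower. At an unadjusted p under 0.05 there were 4680 genes. The 3 old libraries lay beyond all 3 young libraries in 37.3% of the genes tested, where chance gives 10%. The genes named first are the 8 with the largest rise and the 8 with the largest fall among named genes that passed, reached a mean of 1 CPM and had groups without overlap. Ubd, a ubiquitin-like modifier gene, had no count in the young libraries and 92 counts in the old ones, at least 31.8-fold higher against a floor of 3 counts over the group. Cxcl13, a B cell chemokine, had 2 counts in young and 158 in old hearts, a ratio of 80.7 (95% counting interval 22 to 672, exact binomial). The scavenger receptor gene Cd163l1 had a log2 fold change of 6.07 ± 0.82, Csprs of 5.70 ± 0.68 and Apol9b of 5.06 ± 0.51. Csprs and Apol9b belong to families of near-identical copies, so their reads may be split between copies. The 8 genes with the largest fall were Aplnr and 7 others. They are Cngb3 (−2.65 ± 0.30), a cyclic nucleotide-gated channel subunit, Nnat (−2.61 ± 0.69), Ddc (−2.56 ± 0.42), whose enzyme makes dopamine and serotonin, the water channel gene Aqp4 (−2.37 ± 0.39), Cd109 (−2.27 ± 0.66), Pirt (−2.25 ± 0.26) and Zdhhc15 (−2.17 ± 0.49). The count of changed genes was 5570 without old 1, 1541 without old 2, 919 without old 3, and 539, 540 and 619 without young 1, 2 and 3. With 1 library left out the call ended for Zdhhc15 (without young 1, 2 or 3 or old 3), Nnat (without young 1, 2 or 3 or old 2 or 3) and Cd109 (without young 1, 2 or 3 or old 2 or 3) (edgeR adjusted p = 0.0502 to 0.158). Without old 3 the log2 fold change was 5.92 for Slfn4 and 5.26 for Cd163l1, without young 1 7.23 for Csprs, and without old 1 −4.86 for Nnat and −3.88 for Cd109. On the FPKM scale with a pseudocount of 1, which shrinks ratios of low values, it was 2.07 for Snhg11, 2.73 for Slfn4, 1.34 for Cd163l1 and −0.79 for Cngb3. Cd109 also missed the threshold in DESeq2 (adjusted p = 0.112), and Nnat did with the length and GC trend removed and the replicate block (0.0522). Over all settings that left out 1 library, 48 of the 87 called genes that the rule named kept their call, and the others reached an edgeR adjusted p of at most 0.173.

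**Figure D1:**
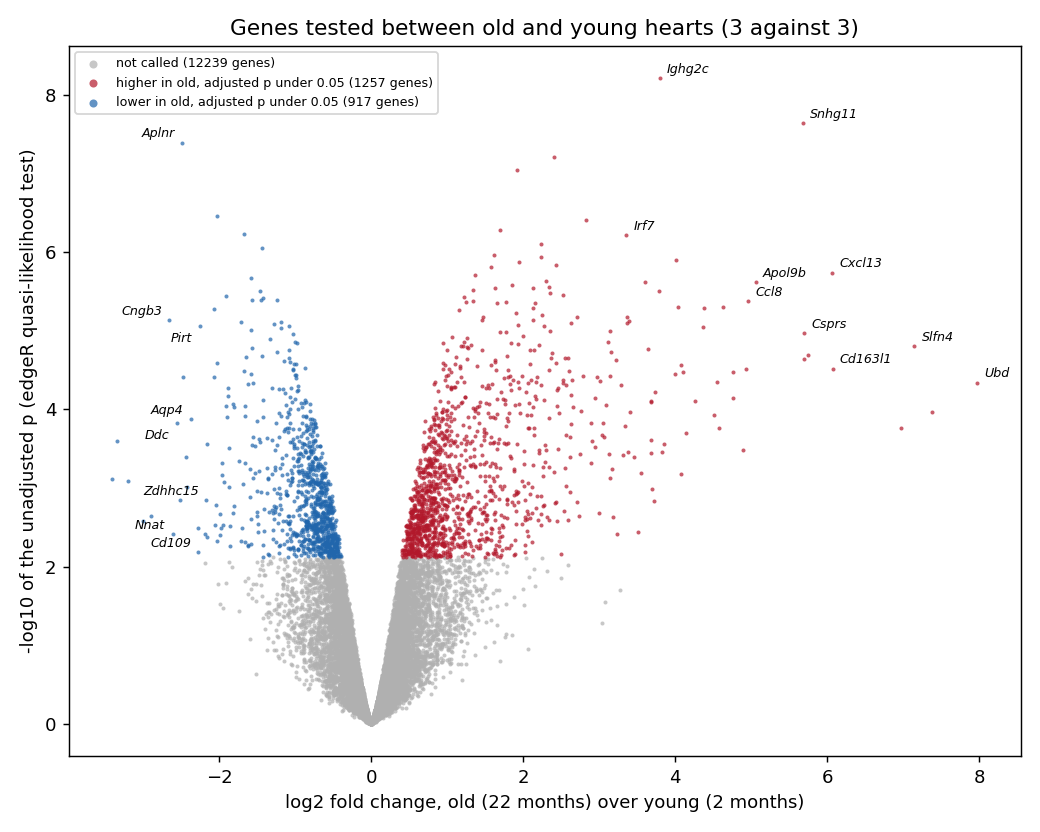
Each point is 1 of 14413 genes tested; the horizontal axis gives the log2 fold change of old over young hearts and the vertical axis −log10 of the unadjusted edgeR p. Red points (1257) were higher and blue points (917) lower in old hearts at an adjusted p under 0.05, and the rises reach further from 0 than the falls; the fitted value of Ubd depends on the prior count.

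Interferon-response genes rose in old hearts as a group. Of 47 tested members 44 were higher and 0 lower, with a median log2 fold change of 2.14, and 47 were higher adjusted over the list alone (camera adjusted p = 6.23e-58, and 0.333 with an estimated correlation). Irf7, a transcription factor that drives interferon production, rose from 31.5 ± 1.01 to 322 ± 143 CPM (3.36 ± 0.29, edgeR adjusted p = 0.000886; ENSMUSG00000025498, chromosome 7, 141262706 to 141266481). Ifi27l2a rose from 20.3 ± 4.36 to 144 ± 40.3 CPM (2.83 ± 0.23). The mean log2 CPM of the list was 3.88 ± 0.13 in young and 5.94 ± 0.58 in old hearts, and the 3 old values (5.47, 5.75 and 6.59) exceeded the 3 young ones (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow).

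Antigen-presentation genes were higher as well, 17 of 20 tested and 17 adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.45e-20, and 0.316 with an estimated correlation). H2-T22 and H2-Q7, which encode class I molecules, had log2 fold changes of 1.36 ± 0.13 and 1.86 ± 0.19; genes of this family resemble each other closely, so reads may be assigned to the wrong member. Of 32 cytokine, chemokine and innate inflammation genes 19 were higher and 1 lower, with 21 higher and 1 lower adjusted over the list alone and a median of 1.19 (camera adjusted p = 2.91e-13, and 0.316 with an estimated correlation). Ccl8 and Cxcl13 led this list. In the complement list 8 of 19 were higher and 0 lower, and 12 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.29e-08, and 0.436 with an estimated correlation). C4b rose from 14.2 ± 6.59 to 196 ± 77.7 CPM (3.79 ± 0.39), with C4a as a near-identical copy. C1qa, a subunit of C1q that macrophages express, rose from 56.6 ± 4.69 to 132 ± 8.3 CPM (1.22 ± 0.13). The complement median was 0.61 without old 1, and 0.55 and 0.57 on the FPKM scale with pseudocounts of 1 and 0.1. Fry, which asks whether the genes of a list moved on balance in the same direction, gave adjusted p values of 0.0366 for the interferon, 0.0349 for the antigen-presentation, 0.0349 for the cytokine and 0.0414 for the complement list.

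Several markers of leukocytes were higher as well. Of 20 macrophage and monocyte markers 7 were higher and 0 lower, likewise 7 adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.11e-05, and 0.436 with an estimated correlation). Ly6c2, a marker of inflammatory monocytes with the close copy Ly6c1, rose from 0.312 ± 0.0371 to 3.36 ± 0.884 CPM (3.39 ± 0.39). Among 12 B and plasma cell markers 3 were higher and 0 lower, and 3 adjusted over the list alone (camera adjusted p = 0.0116, and 0.436 with an estimated correlation). The immunoglobulin constant gene Ighg2c had the smallest p of all genes named and rose from 1.3 ± 0.182 to 18.1 ± 1.01 CPM (3.80 ± 0.20, edgeR adjusted p = 8.90e-05; ENSMUSG00000076612, chromosome 12, 113285325 to 113288932). Igha rose by 1.94 ± 0.44. The constant genes Ighm (0.05 ± 0.21, edgeR adjusted p = 0.895) and Igkc (0.79 ± 0.34, edgeR adjusted p = 0.145) were among the 9 members that did not pass. For T and NK cells 6 markers could be tested; 2 were higher, Trbc1 (2.10 ± 0.46) and Lat (1.34 ± 0.38), and 3 adjusted over the list alone (camera adjusted p = 0.0431, and 0.436 with an estimated correlation). Among 8 neutrophil and mast cell markers 4 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.0367, and 0.576 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 1.75 ± 0.24, and Kit, a receptor of mast cells, fell from 7.23 ± 1.36 to 2.56 ± 0.488 CPM. For the macrophage and monocyte markers list the adjusted p was 0.056 with fry. The B and plasma cell markers list had an adjusted p of 0.141 without old 1, 0.0679 with no filter on low counts and 0.488 with protein-coding genes alone. Restriction to protein-coding genes leaves out Ighg2c, Igha and, from the T and NK cell list, Trbc1, so it removes genes behind these calls. For the T and NK cell markers list the adjusted p was 0.143 without old 1, 0.152 with protein-coding genes alone, 0.0688 with the replicate number as a block, 0.0591 with the length and GC trend removed and 0.0817 with that trend removed and the block. The neutrophil and mast cell markers list had an adjusted p of 0.216 without old 1, 0.147 without old 3, 0.124 with a CPM of at least 1 in at least 3 samples, 0.0515 with the length and GC trend removed and 0.139 with fry. Calls that ended when 1 library was left out were those of Igha (without young 1, 2 or 3), Trbc1 (without young 1, 2 or 3 or old 3) and Lat (without young 1, 2 or 3 or old 2 or 3) (edgeR adjusted p = 0.05 to 0.173). Lat also missed the threshold in DESeq2 (0.0684), limma-voom (0.0552), with no filter on low counts (0.0682) and with the replicate block (0.091, and 0.0925 with the length and GC trend removed), and Igha on the FPKM scale (limma, 0.0505), all adjusted p values.

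**Figure D2:**
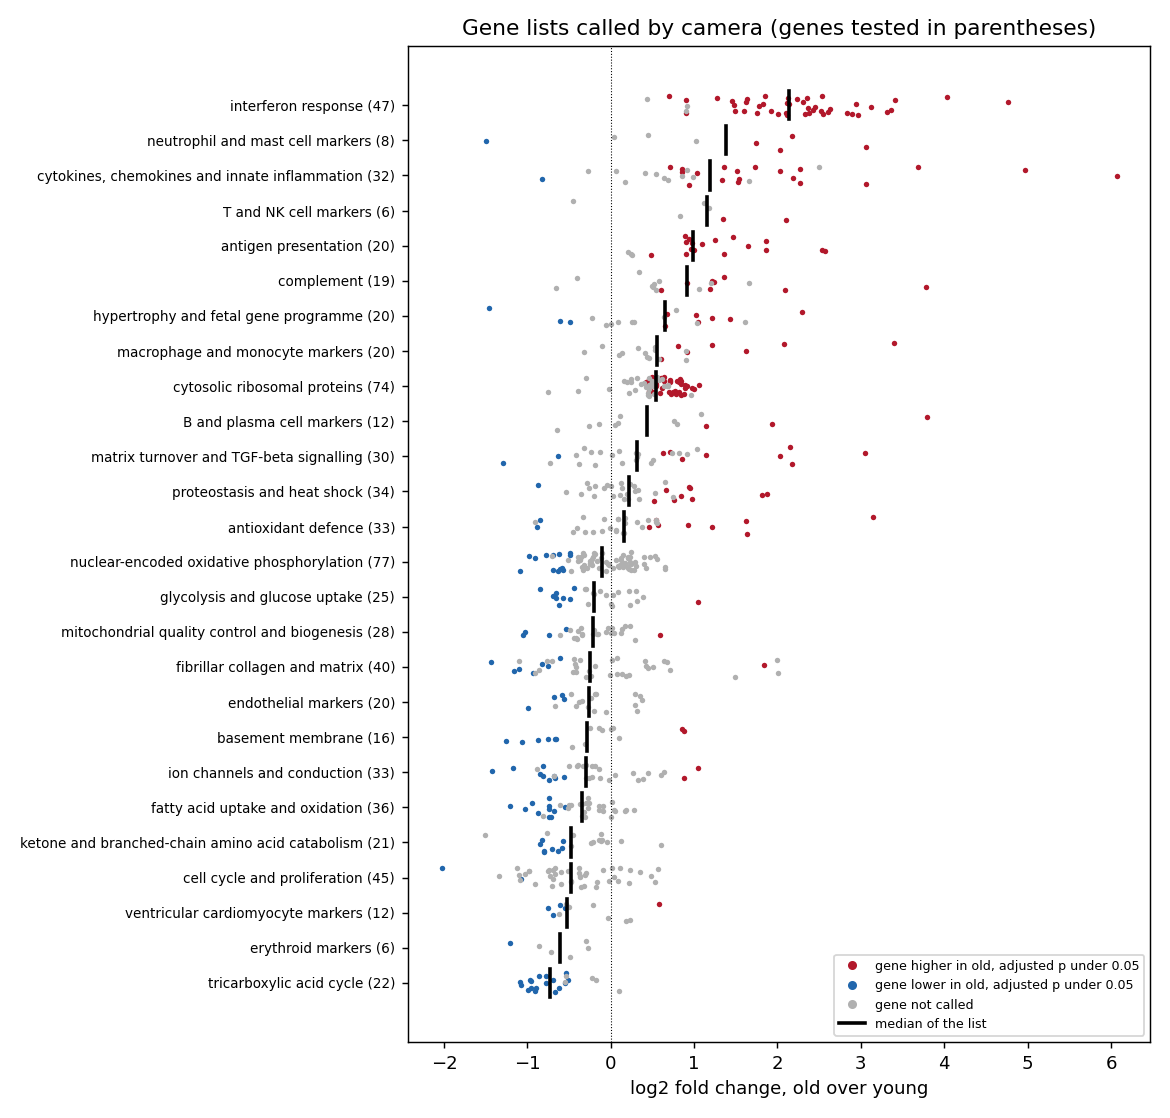
Each point is 1 tested gene of a list, placed by its log2 fold change of old over young hearts; red and blue points passed an edgeR adjusted p of 0.05, grey points did not, and black bars are list medians. The 26 lists called by camera are ordered by median, from the tricarboxylic acid cycle (−0.73) to the interferon response (2.14).

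Genes of mitochondrial fuel oxidation were lower in old hearts. Of 22 tested members of the tricarboxylic acid cycle list 17 were lower and 0 higher, 19 adjusted over the list alone, with a median log2 fold change of −0.73 (camera adjusted p = 2.38e-12, and 0.436 with an estimated correlation; fry adjusted p = 0.0366). Pdhb, a subunit of pyruvate dehydrogenase, fell from 573 ± 12.6 to 295 ± 40.6 CPM (−0.96 ± 0.14, edgeR adjusted p = 0.00384; ENSMUSG00000021748, chromosome 14, 8165996 to 8173025). Sdhd, a subunit of succinate dehydrogenase, fell from 307 ± 15 to 144 ± 33.9 CPM (−1.09 ± 0.17). In the fatty acid list 11 of 36 were lower and 0 higher, 16 adjusted over the list alone, with a median of −0.34 (camera adjusted p = 1.76e-06, and 0.436 with an estimated correlation; fry adjusted p = 0.0366). Ppargc1a, a coactivator of mitochondrial gene expression, fell from 66.2 ± 7.05 to 32.4 ± 3.58 CPM (−1.03 ± 0.14), and the β-oxidation enzyme gene Hadh with a log2 fold change of −0.95 ± 0.19. Ketone and branched-chain amino acid catabolism had 8 of 21 members lower and 0 higher, 12 adjusted over the list alone, with a median of −0.47 (camera adjusted p = 7.39e-05, and 0.436 with an estimated correlation; fry adjusted p = 0.0409). Oxct1, which activates ketone bodies, fell from 618 ± 31.4 to 354 ± 64.5 CPM, and Dbt had a log2 fold change of −0.57 ± 0.12. The call ended with 1 library left out for Hadh (without young 1 or 2), Oxct1 (without young 1, 2 or 3) and Dbt (without young 1, 2 or 3 or old 3) (edgeR adjusted p = 0.0507 to 0.0878). Without old 1 the median of the fatty acid list was −0.56. Dbt also missed the threshold with the length and GC trend removed and the replicate block (edgeR adjusted p = 0.0543).

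Nuclear-encoded genes of the respiratory chain were lower as a list by camera, though 33 of 77 had a log2 fold change above 0. Sdha, Sdhb, Sdhc and Sdhd belong to this list and to the tricarboxylic acid cycle list, so these lists are not independent. Of 77 nuclear-encoded members 13 were lower and 0 higher, 15 adjusted over the list alone, with a median of −0.11 (camera adjusted p = 0.0176, and 0.693 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, fell from 447 ± 47.1 to 226 ± 14.4 CPM (−0.98 ± 0.14). Of 13 mitochondrially encoded genes 1 was higher, mt-Nd3 (0.60 ± 0.13), and 12 did not pass, with 1 adjusted over the list alone (limma's camera adjusted p = 0.208); mt-Co2 had −0.72 ± 0.25 (edgeR adjusted p = 0.078). These transcripts took 24.4% ± 0.953 of counts in young and 20.3% ± 4.49 in old hearts, with 16.1% in old 2 (exact permutation p = 0.3). In the list of mitochondrial quality control and biogenesis 4 of 28 were lower and 1 higher, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0116, and 0.436 with an estimated correlation); Timm23, an import channel subunit, had −1.05 ± 0.22. Glycolysis and glucose uptake had 8 of 25 lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0478, and 0.512 with an estimated correlation). Pdk2, a kinase of pyruvate dehydrogenase, fell from 356 ± 30.7 to 220.3 ± 19.1 CPM, and Pfkfb1 rose from 12.5 ± 1.37 to 25.8 ± 5.78 CPM. Without old 1 the median of the oxidative phosphorylation list was −0.05, with 14 genes higher and 25 lower, and without old 2 it was −0.19. For the nuclear-encoded oxidative phosphorylation list the adjusted p was 0.0802 without young 1, 0.169 without old 1 and 0.302 with fry. The glycolysis and glucose uptake list had an adjusted p of 0.0878 without young 1, 0.0636 without young 3, 0.103 without old 3, 0.0578 with a CPM of at least 1 in at least 3 samples, 0.057 with protein-coding genes alone and 0.0723 with the replicate number as a block. With 1 library left out the call ended for mt-Nd3 (without young 1, 2 or 3 or old 3), Timm23 (without young 1 or 2), Pdk2 (without young 1 or 2) and Pfkfb1 (without young 1) (edgeR adjusted p = 0.0508 to 0.101). For mt-Nd3 it also ended with the length and GC trend removed and the replicate block (edgeR adjusted p = 0.0547).

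Genes of cytosolic ribosomal proteins were higher in old hearts. Of 74 tested members 40 were higher and 0 lower; adjusted over the list alone these were 61 higher and 2 lower, with a median log2 fold change of 0.54 (camera adjusted p = 1.54e-15, and 0.436 with an estimated correlation; fry adjusted p = 0.0366). Rps27a rose from 111 ± 9.8 to 231 ± 35.2 CPM and Rpl36a from 75.5 ± 2.78 to 136 ± 14.9 CPM, and many ribosomal protein genes have processed pseudogenes that can share their reads. Chaperone genes followed, with 9 of 34 members of the proteostasis list higher and 1 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0275, and 0.596 with an estimated correlation). The chaperones Hspa8 and Hsp90b1 had log2 fold changes of 0.94 ± 0.15 and 0.76 ± 0.15. In the antioxidant list 8 of 33 were higher and 2 lower, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0272, and 0.576 with an estimated correlation). Gpx3, an extracellular glutathione peroxidase, rose from 225 ± 9.11 to 693 ± 106 CPM (1.62 ± 0.15), and Srxn1, which restores oxidised peroxiredoxins, from 26.8 ± 4.94 to 83.2 ± 11.2 CPM. Of 30 autophagy and lysosome genes Park2 (1.26 ± 0.15) was higher and 29 did not pass, with 1 adjusted over the list alone (limma's camera adjusted p = 0.893). Ribosomal RNA of mitochondria took 1.18% ± 0.0838 of counts in young and 1.94% ± 0.526 in old hearts, and the nuclear RNA Neat1 0.342% ± 0.0179 and 0.697% ± 0.303 (exact permutation p = 0.1 each, the smallest possible). For the proteostasis and heat shock list the adjusted p was 0.255 without old 1 and 0.107 with fry. The antioxidant defence list had an adjusted p of 0.0572 without young 3, 0.48 without old 1 and 0.11 with fry. Calls that ended when 1 library was left out were those of Hsp90b1 (without young 1 or 2) (edgeR adjusted p = 0.0738).

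Several collagen transcripts were lower in old hearts, while several genes of matrix turnover were higher. Col1a1, the main chain of type I collagen, fell from 89.5 ± 22.4 to 39.9 ± 10 CPM (−1.17 ± 0.23, edgeR adjusted p = 0.0117; ENSMUSG00000001506, chromosome 11, 94936224 to 94953042). Col3a1 fell from 206 ± 68.5 to 96.5 ± 25.3 CPM (−1.10 ± 0.27) and Sparc, a collagen-binding matrix protein, from 607 ± 90.4 to 224 ± 48.5 CPM (−1.44 ± 0.19). In the matrix list 7 of 40 were lower and 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0164, and 0.693 with an estimated correlation). Col15a1 was among the lower (−0.93 ± 0.17), but 17 of the 40 had a log2 fold change above 0. The mean log2 CPM of the list was 5.21 ± 0.40 in young and 5.06 ± 0.50 in old hearts. The ages overlapped in this mean (exact two-sided permutation p = 0.8). Basement membrane genes were lower in 6 of 16 and higher in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0154, and 0.436 with an estimated correlation). Nid1, a linker of laminin and collagen IV, had a log2 fold change of −1.26 ± 0.21, and Col4a5, a collagen IV chain gene, was higher (0.88 ± 0.15). For matrix turnover and TGF-beta signalling 8 of 30 were higher and 2 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0391, and 0.659 with an estimated correlation). The protease gene Mmp3 rose from 3.39 ± 1.16 to 28 ± 22.3 CPM (3.04 ± 0.53; 2.15 without old 1). Of 18 cardiac fibroblast markers 1 was higher, Dpep1, and 1 lower, Col1a1, and the same held adjusted over the list alone (limma's camera adjusted p = 0.272; 0.0339 without young 1 and 0.0301 without old 1). For the fibrillar collagen and matrix list the adjusted p was 0.109 without young 3, 0.325 without old 2 and 0.448 with fry. The basement membrane list had an adjusted p of 0.0742 with fry. For the matrix turnover and TGF-beta signalling list the adjusted p was 0.181 without young 1, 0.451 without old 1, 0.0739 with a CPM of at least 1 in at least 3 samples and 0.254 with fry. The call ended with 1 library left out for Col1a1 (without young 2 or 3 or old 3), Col3a1 (without young 2 or 3 or old 2 or 3), Col4a5 (without young 1) and Dpep1 (without young 1, 2 or 3 or old 3) (edgeR adjusted p = 0.0501 to 0.11). Col3a1 also missed the threshold on the FPKM scale (limma adjusted p = 0.0516 and 0.0516 with the larger and the smaller pseudocount) and with the length and GC trend removed and the replicate block (0.0524).

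Cardiomyocyte genes moved in both directions. Myh7, the slow myosin heavy chain gene expressed in fetal and stressed ventricles, rose from 734 ± 42 to 1698 ± 755 CPM (1.21 ± 0.27, edgeR adjusted p = 0.0187; ENSMUSG00000053093, chromosome 14, 54970684 to 54994626). Myh6, the adult fast chain, fell from 22616 ± 1821 to 13464 ± 1616 CPM (−0.75 ± 0.15, edgeR adjusted p = 0.0123). The natriuretic peptide gene Nppb went from 110.4 ± 19.5 to 227 ± 120.3 CPM and did not pass (edgeR adjusted p = 0.0531; 0.00459 in DESeq2, 0.00162 with no filter on low counts, 0.0438 with the length and GC trend removed, 0.0401 without old 2, and 0.0166 without old 1). Without old 1 the log2 fold change of Nppb was 0.51. Nppa went from 74.8 ± 34.4 to 71.7 ± 66.8 CPM with a log2 fold change of −0.06 ± 0.64. Of 20 genes of the hypertrophy and fetal programme 7 were higher and 3 lower, 9 and 3 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0317, and 0.659 with an estimated correlation). Flnc rose from 174 ± 21.1 to 360.4 ± 48.9 CPM, whereas the skeletal actin gene Acta1, also a member, fell from 486 ± 169.8 to 176 ± 29.2 CPM. Gdf15, a stress-induced cytokine, rose from 0.93 ± 0.31 to 4.59 ± 2.12 CPM (2.29 ± 0.44). The atrial markers Sln, Myl4 and Myl7, of which Myl4 and Myl7 were chosen after their values were seen, had 23, 87.3 and 54 CPM in old 1 and at most 4.08, 20.3 and 13.8 CPM in any other library. Myh7, Nppb and Nppa also had their highest values in old 1 (2546, 366 and 145 CPM). Without old 1 the log2 fold change of Myh7 was 0.79 and the median of the hypertrophy list 0.39. Of 12 atrial markers Stard10 (from 21.1 ± 0.402 to 48.3 ± 12.7 CPM) was higher and 11 did not pass, with 1 adjusted over the list alone (limma's camera adjusted p = 0.438). For the hypertrophy and fetal gene programme list the adjusted p was 0.174 without young 1, 0.376 without old 1, 0.0603 with the length and GC trend removed and 0.293 with fry. With 1 library left out the call ended for Myh7 (without young 1, 2 or 3), Myh6 (without young 1, 2 or 3) and Gdf15 (without young 1 or 2) (edgeR adjusted p = 0.0512 to 0.0855).

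Of 22 adult sarcomere genes 3 were higher and 4 lower, 4 and 6 adjusted over the list alone (limma's camera adjusted p = 0.505). The cardiac actin gene Actc1 fell from 5481 ± 180.5 to 2329.9 ± 415 CPM and Tcap, which caps titin, rose from 1706 ± 175 to 3573 ± 654 CPM. Calcium-handling genes were higher in 2 of 27 and lower in 3, 3 and 5 adjusted over the list alone (limma's camera adjusted p = 0.272). Atp2a2, the pump that refills the sarcoplasmic reticulum, fell from 5445 ± 246 to 3650.4 ± 358 CPM (−0.58 ± 0.14), and the sodium-calcium exchanger gene Slc8a1 rose by 1.16 ± 0.24. Ion channels and conduction had 9 of 33 lower and 2 higher, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0136, and 0.333 with an estimated correlation; fry adjusted p = 0.0349). Scn4b, a sodium channel subunit gene, was among the higher (1.05 ± 0.20). Of 12 ventricular markers 4 were lower and 1 higher, 6 and 1 adjusted over the list alone, with a median of −0.52, and −0.34 without old 2 (camera adjusted p = 0.0352, and 0.436 with an estimated correlation); Pln, the inhibitor of the calcium pump, fell by 0.61 on the log2 scale. Among 8 skeletal muscle markers 2 were lower, Acta1 and Ckm (−0.80 ± 0.15), likewise adjusted over the list alone (limma's camera adjusted p = 0.314). For the ventricular cardiomyocyte markers list the adjusted p was 0.0802 without young 1, 0.0623 without old 1, 0.0551 without old 2 and 0.0579 with the length and GC trend removed. Calls that ended when 1 library was left out were those of Atp2a2 (without young 1, 2 or 3 or old 3), Slc8a1 (without young 1 or 2 or old 3), Scn4b (without young 1), Pln (without young 1, 2 or 3 or old 2 or 3) and Ckm (without young 1) (edgeR adjusted p = 0.0527 to 0.116).

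**Figure D3:**
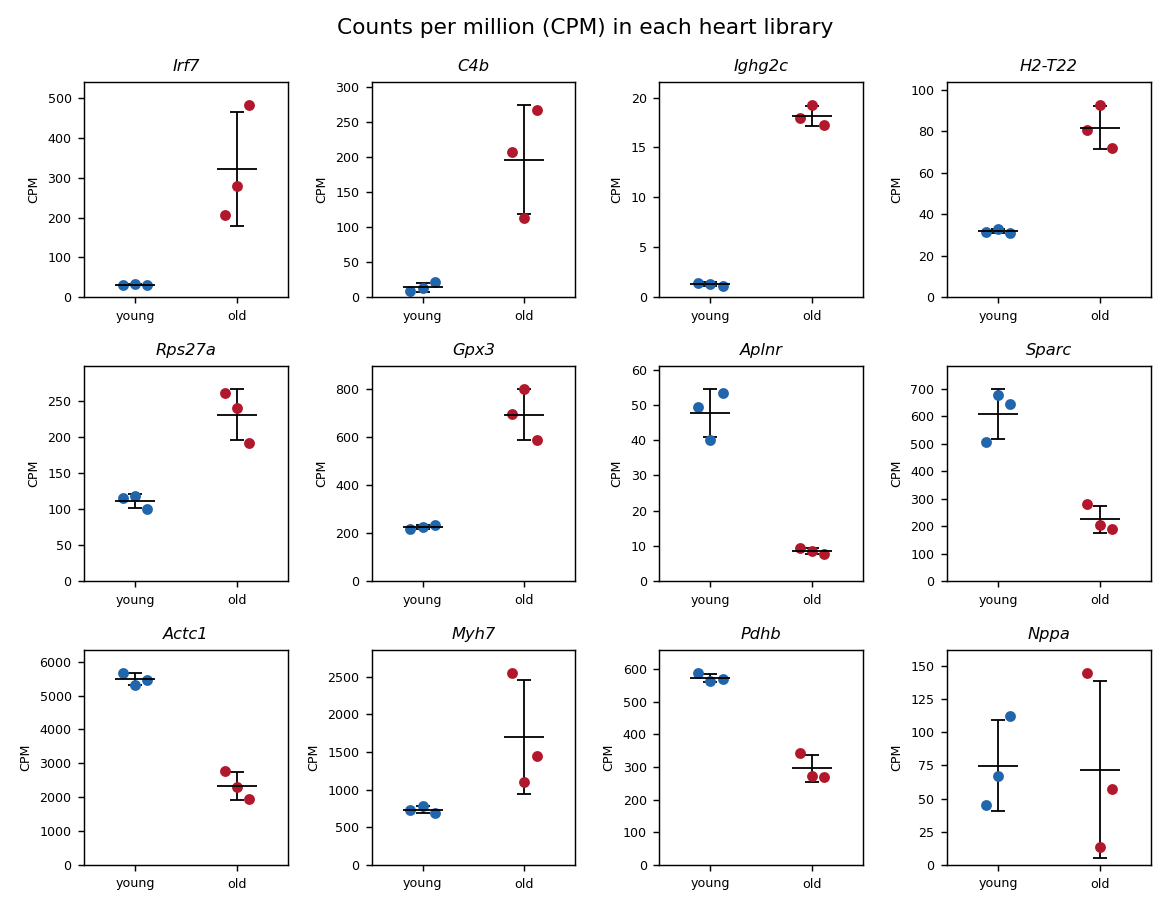
CPM in each of the 3 young (blue) and 3 old (red) libraries for 12 genes, each on its own linear axis starting at 0, with bars at the mean ± SD. The old and young libraries do not overlap for 11 of the genes; for Nppa they do, with means of 74.8 and 71.7 CPM.

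Endothelial, erythroid and proliferation genes were lower by camera. Of 20 endothelial markers 4 were lower and 0 higher, 6 adjusted over the list alone, with a median of −0.26 (camera adjusted p = 0.0184, and 0.436 with an estimated correlation; fry adjusted p = 0.0366). Cdh5, the cadherin of endothelial junctions, fell from 355 ± 21.6 to 178 ± 1.93 CPM, and the water channel gene Aqp1 from 863 ± 35.8 to 539 ± 18.6 CPM. Among 6 erythroid markers 1 was lower, Alas2 (−1.21 ± 0.35), the same adjusted over the list alone (camera adjusted p = 0.0343, and 0.576 with an estimated correlation); Hbb-bt, a haemoglobin chain gene, had −0.86 ± 0.40 (edgeR adjusted p = 0.169). Of 45 cell cycle genes Top2a (−2.03 ± 0.56) and Prc1 (−1.07 ± 0.30) were lower and 43 did not pass, with 0 adjusted over the list alone (edgeR, 10 at an unadjusted p under 0.05) and a median of −0.47 (camera adjusted p = 0.0116, and 0.657 with an estimated correlation). Without young 2 the median of the cell cycle list was −0.19, and on the FPKM scale with a pseudocount of 1 it was −0.26. Top2a had a log2 fold change of −2.95 without old 1. For the endothelial markers list the adjusted p was 0.0935 without old 1. The erythroid markers list had an adjusted p of 0.235 without old 1, 0.12 without old 2 and 0.23 with fry. For the cell cycle and proliferation list the adjusted p was 0.101 without young 2 and 0.231 with fry. The call ended with 1 library left out for Aqp1 (without young 1 or 2), Alas2 (without young 1, 2 or 3 or old 2), Top2a (without young 1, 2 or 3 or old 2 or 3) and Prc1 (without young 1, 2 or 3 or old 3) (edgeR adjusted p = 0.0522 to 0.17). Alas2 (0.0542) and Prc1 (0.0519) also missed the threshold with the length and GC trend removed, Alas2 on the FPKM scale with the smaller pseudocount (limma, 0.0528), and Top2a with the replicate block (0.0533, and 0.0605 with the trend removed), all adjusted p values.

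Senescence genes split. Cdkn2a, whose products include the cell cycle inhibitor p16, rose from 0.268 ± 0.181 to 1.14 ± 0.369 CPM (2.06 ± 0.55, edgeR adjusted p = 0.0355; ENSMUSG00000044303, chromosome 4, 89274471 to 89294653). Cdkn1a, which encodes p21, went from 148 ± 41.5 to 190.3 ± 18.3 CPM with a log2 fold change of 0.36 ± 0.19 (edgeR adjusted p = 0.229). Of 31 senescence and p53 target genes 6 were higher and 3 lower, 7 and 5 adjusted over the list alone (limma's camera adjusted p = 0.842); Ccng1 had a log2 fold change of −0.77 ± 0.13. Circadian clock genes were higher in 3 of 20 and lower in 3, 5 and 3 adjusted over the list alone (limma's camera adjusted p = 0.859). Among the higher were the clock repressors Nr1d2 (0.99 ± 0.16) and Per2 (1.06 ± 0.22). Of 25 immediate early genes 5 were higher and 1 lower, 5 and 2 adjusted over the list alone (limma's camera adjusted p = 0.767); Nr4a1 fell from 37.4 ± 10.8 to 12 ± 1.5 CPM and Ier3 rose from 20 ± 2.42 to 38.2 ± 6.53 CPM. Pericyte and smooth muscle markers were higher in 2 of 14 and lower in 2, 3 and 4 adjusted over the list alone (limma's camera adjusted p = 0.767). Nerve and Schwann cell markers had 1 of 9 lower (Cadm4, −0.77 ± 0.16), mesothelial and epicardial markers 1 of 7 higher (Rspo1, 2.62 ± 0.50), and adipocyte and valve markers 0 of 7 each, with the same counts adjusted over the list alone (limma's camera adjusted p = 0.981, 0.464, 0.882 and 0.1). The valve list passed with no filter on low counts (0.0209) and without young 2, young 3, old 2 or old 3 (0.00745 to 0.0493). Of the lymphoid tissue list 1 gene and of the lung list 2 genes could be tested, too few for camera; Hopx (−0.71 ± 0.13) was lower. With 1 library left out the call ended for Cdkn2a (without young 1, 2 or 3 or old 2 or 3), Per2 (without young 2 or 3 or old 3), Ier3 (without young 2), Cadm4 (without young 1, 2 or 3 or old 3), Rspo1 (without young 1 or 3) and Hopx (without young 1) (edgeR adjusted p = 0.0532 to 0.149). Without young 2 the log2 fold change of Cdkn2a was 2.72. Cdkn2a also missed the threshold with the replicate block (edgeR adjusted p = 0.0514, and 0.0653 with the length and GC trend removed too).

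Over all 41 lists with at least 5 tested members, camera called 26, of which 13 were higher and 13 lower. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry called 15, all of them among the 26. The 9 other splits of the 6 libraries into 3 and 3 each gave 0 changed genes by edgeR. By camera they gave 7, 21, 20, 8, 20, 21, 20, 12 and 14 lists. Camera at the preset correlation thus called many lists for groupings that mix the ages, so its calls alone are weak evidence of an age difference. The median, the mean and the camera direction differed in sign for 9 lists, none of them called: adult sarcomere, calcium handling, autophagy, circadian clock, immediate early, pericyte, adipocyte, nerve and skeletal muscle. Without old 1 the number called by camera was 16.

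Outside the rule for named genes, and chosen after the values were seen, 2 genes of chromosome 19 were lower in all old libraries with little spread. Ide, which encodes insulin-degrading enzyme, went from 125 ± 3.5 to 59.2 ± 5.61 CPM (log2 fold change −1.08 ± 0.13, edgeR adjusted p = 0.00183; ENSMUSG00000056999, chromosome 19, 37268743 to 37337852). Fgfbp3, a carrier of fibroblast growth factors, went from 7.32 ± 0.306 to 1.77 ± 0.573 CPM (log2 fold change −2.03 ± 0.27, edgeR adjusted p = 0.00297; ENSMUSG00000047632, chromosome 19, 36917550 to 36919615). Between them lie 3 tested genes: Btaf1, higher (0.91 ± 0.23), Cpeb3 (−0.12 ± 0.25) and March5 (0.16 ± 0.13), neither of which passed.

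**Figure D4:**
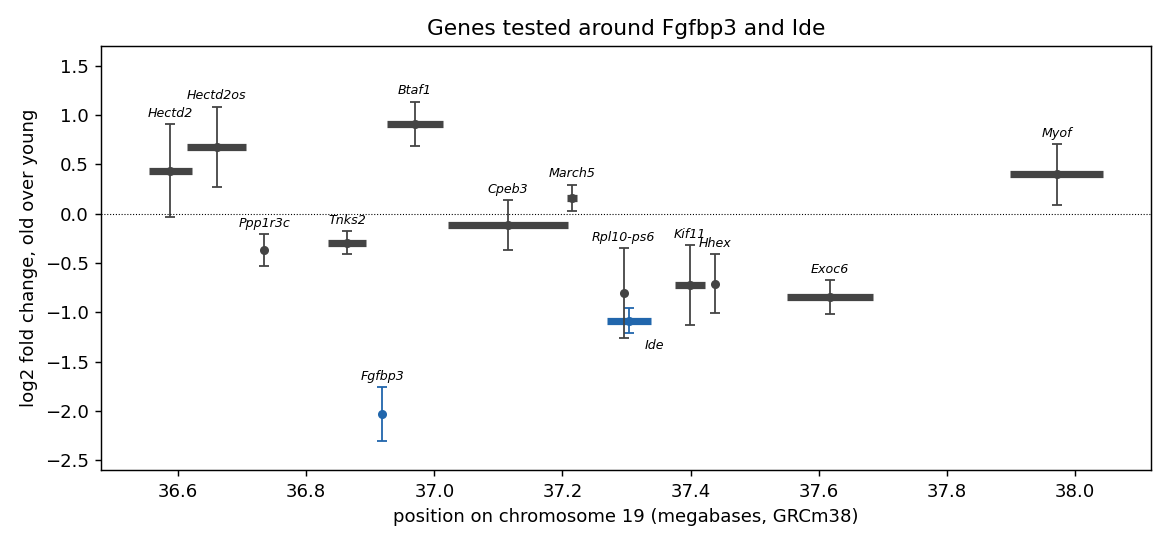
Log2 fold change of old over young hearts ± SE for genes tested on chromosome 19 around Fgfbp3 and Ide (both in blue), drawn as bars from gene start to gene end. The 3 genes between the pair lie at 0.91, −0.12 and 0.16.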

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

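The test of these models was chosen only after their counts were seen. Gene models without a name had been left out of all comparisons above. Of 345 tested, 56 were higher and 12 lower in old hearts at an edgeR adjusted p under 0.05. Of the 14413 named genes tested, 2174 (15.1%) had changed, 1257 higher and 917 lower. The models without a name took 0.3% of counts in young and 0.36% in old libraries. No explanation was tested.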

How the results depend on the processing

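The tests chosen only after the result was seen were those with gene models without a name included and those with the length and GC trend removed, alone or with the replicate block. The 2174 genes called kept their sign in each alternative that tested them, and the number changed was 2163 with RLE size factors, 2212 with upper-quartile factors, 2192 without mitochondrially encoded genes, 2857 with no filter on low counts, 2132 with a CPM of at least 1 in at least 3 samples, 2098 for protein-coding genes, 2702 in DESeq2, 2016 in limma-voom, 1615 and 1620 on the FPKM scale with pseudocounts of 1 and 0.1, 1774 with the replicate number as a block, 2227 with models without a name, 2549 with the trend removed and 1930 with the trend removed and the block. The kept signs say little, since old and young libraries did not overlap in 2164 of the 2174 genes. Deviations of libraries with the same number had correlations of −0.0867, −0.0697 and 0.0332 across genes, so the numbers gave no sign of pairing. On the FPKM scale with a pseudocount of 1, which shrinks ratios of low values, the genes changed at least 2-fold numbered 315.

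With 1 library left out the number of genes changed was 539 to 5570, higher 350 to 2961, lower 184 to 2609 and genes changed at least 2-fold in old hearts 397 to 1535. The highest came without old 1 and the lowest without young libraries, which leaves 2 libraries at that age. Camera called 16 to 26 lists, with the lowest number without old 1. With an estimated correlation 0 lists were called, and fry called 15. Reversals of direction concerned Nppa and lists that were not called. Nppa ranged from −1.09 to 0.43 in log2 fold change (−0.06 with all libraries). The nerve and Schwann cell list reversed with upper-quartile factors (adjusted p = 0.956), no filter (0.63), protein-coding genes (0.991), the block (0.917), the trend removed with the block (0.903) and fry (0.888). The pericyte list did with the block (0.6998) and the trend removed with the block (0.839). Lists that reversed with 1 library left out had limma camera adjusted p values of 0.49 to 0.974 (nerve), 0.281 to 0.889 (pericyte), 0.419 to 0.959 (autophagy), 0.313 to 0.814 (senescence), 0.627 to 0.973 (circadian), 0.358 to 0.802 (immediate early), 0.0301 to 0.956 (fibroblast), 0.46 to 0.973 (adipocyte) and 0.144 to 0.973 (atrial). These ranges take in settings without a reversal. At its lowest camera adjusted p, 0.0301 without old 1, the fibroblast list kept its direction. For all of the reversals the cause was not tested. In data simulated at this depth, edgeR recovered 6% of 67 genes changed 1.5-fold, 52.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold. The simulation gave both ages the same spread, whereas the median SD was 0.14 in young and 0.27 in old hearts. It also changed far fewer genes than the 2174 called here. These shares therefore need not hold for the hearts.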

Other observations

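The tests chosen only after the result was seen were the leukocyte test, the sarcomere test, the removal of the length and GC trend and the test of the genes between Fgfbp3 and Ide. Apln, Ide, Fgfbp3 and the imprinted genes were singled out after values were seen. Apln, which encodes the ligand of Aplnr, was lower too, with a log2 fold change of −1.80 ± 0.28 (edgeR adjusted p = 0.00509). Because Nnat is imprinted, the hypothesis that imprinted growth genes are lower in old hearts as a set was tested. Of 18 tested 5 were lower, 1 was higher and 13 lay below 0, with a median of −0.35, a limma camera p of 0.0024 and a p of 0.0924 with an estimated correlation. Without Nnat the limma camera p was 0.00722 and the median −0.29. The list was written after gene values were seen, which leaving out Nnat does not undo, and these p values are unadjusted. They therefore do not decide the hypothesis.

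The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 2174 changed genes by edgeR, 1257 higher, 917 lower and 818 changed at least 2-fold. The highest other value was 0 for each. Camera called 26 lists in the real split and 7 to 21 in the others. Each other split mixes young and old libraries, which puts the age difference into the spread within groups. The 0 is thus not the count expected without an age difference, and neither are the 7 to 21 lists.

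Interferon-response genes were higher in old hearts (median 2.14). A single old library as the source is argued against by the lowest median with 1 old library left out, 1.90. More leukocytes of unchanged state would raise pan-leukocyte genes by at least as much. These had a median of 0.80 (SD 0.44, 18 genes), against 2.14 (SD 0.86, 47 genes) for the interferon-response genes. The permutation p across genes was 1.00e-05, the smallest possible. It treats genes of the same 6 libraries as independent, so it does not measure the spread between animals. A change of state in leukocytes or other heart cells, a rise of 1 leukocyte type, infection or housing, and age itself stay open and may act together.

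Genes of the tricarboxylic acid cycle were lower (median −0.73). With each library's trend on exon length and GC removed the median was −0.70, and that of the ribosomal protein genes was 0.55, which argues against this trend as the whole source of either. A smaller share of cardiomyocyte RNA would lower adult sarcomere genes by as much, but their median was 0.0257 (SD 0.53, 22 genes). The permutation p across genes, 0.00011, treats genes as independent and does not measure the spread between animals. The sarcomere genes moved in both directions, with 4 lower, 3 higher and log2 fold changes from −1.23 to 1.07. Their median therefore cannot decide whether the share was smaller. The ventricular markers, which share Myh6, Myl2 and Myl3 with the sarcomere list, had a median of −0.52, in the direction of a smaller share. A smaller share may account for a part or all of the fall, and a change within cardiomyocytes with age stays open too.

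Ide and Fgfbp3 were lower in all 3 old libraries. A copy-number difference confined to a segment holding both genes would by itself leave their neighbours in place. The 4 nearest tested genes on each side had a median absolute log2 fold change of 0.56. This cannot decide the question, since 1 of the 8 was called and SEs ran from 0.116 to 0.469. Neighbours may also change for reasons of their own. The loss of 1 unbroken segment is argued against by the genes between, with a median of 0.16, and reads shared between the genes by 0 shared bases. Separate copy changes of each gene, and a change in regulation with age, could each give the fall and were not tested.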
